A study of Mus musculus with 12 samples.

How the data were processed

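Small RNA was sequenced from the striatum of mice, 12 libraries in 4 groups of 3. The groups were wild type (WT) and R6/2 mice, the latter a transgenic model of Huntington's disease, each injected in the striatum with an adeno-associated virus (AAV) that carried either a control construct or a short hairpin RNA against TRAX (shTRAX). TRAX is encoded by Tsnax. The mice were injected at 5 weeks and sampled at 10.5 weeks of age, per the labels. The labels name TRIzol or a column kit for RNA extraction without saying which was used for which sample, and a library kit that adds molecular identifiers. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic and the genome build GRCm38 were used. The aligner, the counter, the use of the molecular identifiers and the authors' test are not given in the sources used here.

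The deposited tables held raw read counts for 2059 pairs of mature miRNA and precursor in every library, per the file headers. The authors also deposited RPM values (reads scaled to a common column total), which differed from count over column total by at most 0.118. The authors' deposited p-value and adjusted p-value columns and their signed fold changes (shTRAX over control, a fall written as minus the inverse ratio) were read only as the authors' own results. A deposited list of 83 miRNAs for R6/2 was read in the same way. The 2 reduced sheets of the tables were not used here. No per-sample column was left without a sample.

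A mature miRNA with several precursors had a row for each, and 81 of the 1915 mature names did. The row with the highest mean was kept, since of the 56 such names that were tested 43 had rows within 5% of each other in every library. Deposited columns summed to 23462100 to 28589800 counts, and the kept values to 13849800 to 16907900 per library. Pairs of libraries of a group differed by a chi-square per degree of freedom of 27.0 to 1674 over 719 to 756 miRNAs, which is more than counting error gives, but abundant miRNAs dominate that value and it was not split by level. Counts were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, filterByExpr with a minimum count of 10, Benjamini-Hochberg adjustment, threshold 0.05). The shTRAX effect was fitted within each genotype over 6 libraries. The genotype difference under each AAV and the difference of the shTRAX effect between genotypes were fitted over all 12 libraries, so that they share 1 estimate of the spread. Levels are TMM-scaled counts over library totals (CPM), as mean ± SD over 3 libraries, and log2 fold changes are given ± SE. CPM here was computed from the counts and is not the deposited RPM.

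A total of 20 lists of miRNAs, written from general knowledge, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, if at least 3 members were tested. They were neuron-enriched, REST-repressed and activity-induced miRNAs, the Dlk1-Dio3 cluster, the let-7, miR-29, miR-30, miR-125 and miR-99/100, miR-181 and miR-34/449 families, miR-17-92 and its paralogues, and markers of oligodendrocytes, astrocytes, microglia and inflammation, blood cells, vessels, choroid plexus and ependyma, hindbrain and spinal cord (Hox clusters), epithelium and olfactory tissue, and muscle. Lists overlap: miR-132 and miR-212 stand in 3 of them. The tests were run again with an estimated correlation and with fry. Minor and major arms of hairpins were compared by the median difference of log2 fold change and by an exact two-sided permutation of libraries on the mean log2 ratio, for which 0.1 is the smallest p that 3 against 3 libraries allow.

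The groups, tests, lists, most of the alternatives and the rule for naming miRNAs were fixed before the data were examined. The rule takes up to 12 higher and 12 lower miRNAs by smallest p among those past the threshold, or, if fewer than 10 pass, 5 higher and 5 lower by unadjusted p as values only. It also takes up to 4 members of each list, the 3 highest and 3 lowest folds of the deposited list, and 5 miRNAs for the difference between genotypes. Members are named here for each list that passed the set test. Genomic clusters as sets, GC correction, merging of miRNAs with near-equal counts, library weights and the mean shTRAX effect over both genotypes were added after the data were seen. Alternatives covered scaling, filters, DESeq2 1.42.0, limma on log2(RPM + 1), the repeated precursor rows, the replicate number as a block, the libraries in the fit, and leaving out each library.

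Positions come from GENCODE release 21 of the mouse genome, build GRCm38, where 1172 of 1193 precursors were found by name. Clusters join at least 5 precursors no more than 10000 bases apart. GC content is that of the precursor arm, a stand-in for the mature sequence. The procedures were tested on simulated counts with 200 changed miRNAs and the spread of the fit over 12 libraries. Recovery was scored only over changed miRNAs that passed the expression filter, for R6/2 96 with a log2 change of 1 and 88 with 2. For log2 changes of 1 and 2, edgeR recovered 67.7% and 95.5% for the shTRAX effect in R6/2, 67.7% and 93.6% in WT, 68.4% and 95.0% for the genotype difference under control AAV, 63.6% and 94.9% under shTRAX AAV, and 34.0% and 84.7% for the difference of effects. The biological coefficient of variation was 0.310 in the R6/2 fit and 0.192 in the WT fit against 0.260 in the simulation. Recovery may thus be overstated for R6/2 and understated for WT, but those spreads were not simulated. Figures were drawn with matplotlib 3.10.9.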

Results

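The data were miRNA counts from 12 samples of mouse striatum, 3 in each of 4 groups: WT with control AAV, WT with shTRAX AAV, R6/2 with control AAV and R6/2 with shTRAX AAV. R6/2 is a transgenic model of Huntington's disease, and TRAX is the partner of translin in an RNA-binding complex with RNase activity. Libraries held 13849800 to 16907900 counts on mature miRNAs. Between 1033 and 1106 miRNAs were detected per library, and 689 passed the expression filter over all libraries. The 10 most abundant miRNAs took 52.3% to 60.8% of the counts. Tsnax mRNA is not measured in miRNA data, so the knockdown itself was not checked here. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples.

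The library labelled R6/2 shTRAX replicate 3 stood apart from the other 11. Its score on the first principal component, which held 34.2% of the variance, was 24.5 against -5.54 to 0.38 in the others, and its median correlation with its own group was 0.968. Its log2 ratio to the mean of the other libraries of its group rose with arm GC content across 683 miRNAs, with a Spearman rho of 0.47 (miRNAs are not independent replicates). A GC trend also parted the control groups of the 2 genotypes. The Spearman rho of a library's log2 deviation from the mean of the 12 with arm GC content was -0.36 to -0.30 in the R6/2 controls and 0.04 to 0.19 in the WT controls, and -0.23, -0.17 and 0.42 in R6/2 shTRAX replicates 1, 2 and 3 against -0.08 to 0.06 in the WT shTRAX libraries. miR-142a-3p, a miRNA of blood-derived and microglial cells, varied widely within groups, from 232 to 4706 CPM over the 12 libraries. Markers of choroid plexus and ependyma also varied, from 2271 summed CPM in R6/2 control replicate 1 to 9273 in R6/2 control replicate 2.

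**Figure D1:**
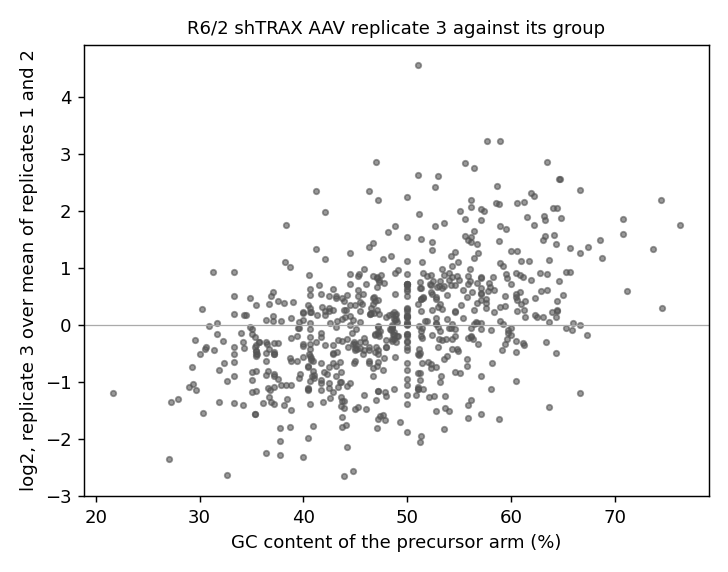
Each point is a miRNA, with the GC content of its precursor arm (%) on the x axis and, on the y axis, the log2 ratio of R6/2 shTRAX replicate 3 to the mean of replicates 1 and 2. GC-rich arms tended to be higher in replicate 3, with a Spearman rho of 0.47 over 683 miRNAs.

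The first question was which miRNAs differ under shTRAX in R6/2 striatum. No single miRNA passed the threshold. Among higher values, those with the smallest unadjusted p included miR-412-5p (log2 fold change 1.33 ± 0.25), which went from 32.0 ± 3.2 to 79.6 ± 27 CPM, and miR-496a-3p (1.11 ± 0.28), from 95.9 ± 15 to 203 ± 63 CPM (SD, n = 3 per group). Both, with miR-409-3p (0.89 ± 0.21), lie in the imprinted Dlk1-Dio3 region of chromosome 12, as does miR-376c-3p among the lower values below, and the 87 tested members of that cluster were balanced (44 above 0, 43 below, median 0.02, camera adjusted p = 0.40). miR-93-3p stood at 0.79 ± 0.20, and miR-6904-5p at 49 counts over the shTRAX libraries against 3 over the controls, a ratio of 16.4 with a 95% exact Poisson interval of 5.29 to 82.2 that covers counting error only. All 3 of those control counts came from R6/2 control replicate 3, so no ratio can be given without that library, and the fitted log2 fold change (3.90) ran from 0.68 to 7.05 over the alternatives (DESeq2 adjusted p = 0.0181). Among lower values, the smallest p belonged to miR-376c-3p (-0.72 ± 0.14), miR-3964 (-2.06 ± 0.52), miR-669k-5p (-0.76 ± 0.20), miR-466c-5p (-1.52 ± 0.42) and miR-203-3p (-0.76 ± 0.21). edgeR gave 0 of 651 miRNAs at an adjusted p under 0.05, with a smallest adjusted p of 0.421, 68 at an unadjusted p under 0.05, and DESeq2 gave 13 (9 higher, 4 lower). Values of the groups did not overlap for 30.4% of miRNAs, where chance gives 10%. The 68 became 37, 37 and 28 without R6/2 control replicates 1, 2 and 3 and 105, 82 and 114 without shTRAX replicates 1, 2 and 3. The adjusted count was 3 without R6/2 control replicate 2 and 4 without R6/2 shTRAX replicate 3, and the 4 included miR-496a-3p (adjusted p = 0.0167), miR-412-5p (0.0234) and miR-376c-3p (0.0236).

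In the authors' deposited table for R6/2, 1 row had an adjusted p under 0.05, miR-412-5p with a fold of 2.46 (adjusted p = 0.0069). The authors' deposited list of 83 miRNAs for R6/2 held 56 with a higher and 27 with a lower fold. All 83 had the same sign in the edgeR fit, which used the same counts, 52 at an unadjusted p under 0.05 and 0 at an adjusted one. The list was chosen on these samples, so this is not independent evidence. Without R6/2 shTRAX replicate 3, 81 of 83 had that sign. The largest folds of the authors' deposited list were 3.53 for miR-501-3p, 3.47 for miR-370-3p and 3.46 for miR-760-3p. R6/2 shTRAX replicate 3 was the high library for all 3. miR-501-3p stood at 28.2 CPM there against 3.70 and 3.96 in the other shTRAX libraries of R6/2 and miR-370-3p at 462 against 65.1 and 72.1, and the edgeR log2 fold change of miR-760-3p went from 1.84 to -0.06 without it. The lowest folds of the authors' deposited list were -4.31 for miR-3964, -4.15 for miR-155-5p, an inflammatory miRNA, and -3.34 for miR-142a-3p.

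None of the 19 lists tested in R6/2 passed under shTRAX (adjusted p from 0.0789 to 0.93). Nearest were the miR-125 and miR-99/100 family, with 9 of 11 members above 0 and a median of 0.43, and the microglia and inflammation markers, with 3 of 13 above 0 and a median of -0.73 (both adjusted p = 0.0789; 0.813 with an estimated correlation). No member of these or the other lists passed, and 0 did when adjusted over the list alone. The hindbrain and spinal Hox list had 2 tested members and was not tested. Without R6/2 shTRAX replicate 3, 2 lists passed, let-7 (adjusted p = 0.0139) and miR-125 and miR-99/100 (0.00171), the microglia and inflammation markers passed without R6/2 control replicate 1 (1.98e-06), and the choroid plexus and ependyma markers passed without R6/2 control replicate 2 (2.38e-08), the library with the most of them. With GC offsets the microglia and inflammation markers passed (0.0328).

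The same question was asked in WT striatum. miR-496a-3p rose under shTRAX, from 88.2 ± 4.4 to 203 ± 25 CPM (log2 fold change 1.20 ± 0.12, adjusted p = 0.0090), with all 3 shTRAX libraries (176 to 226 CPM) above all 3 controls (84.0 to 92.8 CPM). Its hairpin lies in an intron of Mirg on chromosome 12, at 109739119 to 109739197 (GRCm38). Next by p among higher values were miR-412-5p, from an exon of Mirg, which stood at 47.8 ± 2.6 and 87.1 ± 13 CPM (0.86 ± 0.14, adjusted p = 0.0836), miR-1197-3p (1.08 ± 0.23), miR-216a-5p (0.78 ± 0.18) and miR-667-5p (0.57 ± 0.14). Among lower values, the smallest p belonged to miR-3535 (-0.63 ± 0.13), miR-187-5p (-0.84 ± 0.20), miR-671-5p (-0.62 ± 0.17), miR-383-5p (-0.38 ± 0.11) and miR-299b-5p (-0.40 ± 0.13). edgeR thus called 1 of 665 miRNAs, with 50 at an unadjusted p under 0.05, and DESeq2 called 4 (2 higher, 2 lower). The authors' deposited table for WT had 4 rows at an adjusted p under 0.05, with folds of 2.30 for miR-496a-3p, 1.84 for miR-412-5p, -1.76 for miR-187-5p and -1.52 for miR-3535. Groups did not overlap for 15.0% of miRNAs (10% by chance). The 50 became 204 without WT shTRAX replicate 1 and ran from 24 to 52 without any other library. The call of miR-496a-3p was lost without any 1 of the WT controls or without WT shTRAX replicate 2 (count 0; adjusted p up to 0.203), while 2 miRNAs passed without WT shTRAX replicate 3. Without WT shTRAX replicate 1, 57 passed (23 higher, 34 lower), among them miR-412-5p (adjusted p = 0.0145), miR-1197-3p (0.0435), miR-216a-5p (0.0221), miR-3535 (0.0145), miR-187-5p (0.0142), miR-671-5p (0.0198) and miR-383-5p (0.0221).

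Among the lists, members of the Dlk1-Dio3 cluster, a large imprinted miRNA cluster, were higher as a set in WT under shTRAX. Of 88 tested members 62 lay above 0, the median was 0.12, and 1 passed over all miRNAs and 3 adjusted over the list alone (camera, adjusted p = 1.1e-05; adjusted p = 0.509 with an estimated correlation). Choroid plexus and ependyma markers were higher as a set, with 13 of 14 above 0 and a median of 0.44 (adjusted p = 0.00251; 0.509 with an estimated correlation). Their members miR-448-3p (1.22 ± 0.39), miR-1298-5p (1.51 ± 0.58), miR-204-5p (0.88 ± 0.33) and miR-1264-5p (0.50 ± 0.22) did not pass. The hairpins of miR-448, miR-1298 and miR-1264 all lie in introns of Htr2c, so these members are not independent. The summed CPM of the list was 6128, 3910 and 2289 in the 3 shTRAX libraries against 2297 to 2673 in the controls. miR-448-3p passed without WT shTRAX replicate 3 (adjusted p = 0.0462). Neuron-enriched miRNAs were lower as a set, with 7 of 32 above 0 and a median of -0.09 (adjusted p = 0.0101; 0.509 with an estimated correlation). Its members miR-383-5p, miR-138-1-3p (-0.26 ± 0.11), miR-218-2-3p (-0.25 ± 0.13) and miR-212-3p (-0.27 ± 0.13) did not pass, although miR-212-3p did without WT shTRAX replicate 1 (0.0435). No member of these 2 lists passed adjusted over the list alone. The other 17 lists had adjusted p from 0.0753 to 0.959. Without WT shTRAX replicate 1 the choroid (0.256) and neuron-enriched (0.179) sets did not pass, while miR-29 (0.0314) and the microglia markers did. The latter also passed without WT control replicate 1 (lowest 0.00418), vascular markers passed without WT control replicate 3 (0.0211), and epithelial and olfactory markers without WT control replicate 3 or WT shTRAX replicate 3 (lowest 2.97e-06). With GC offsets the vascular markers passed (0.0347).

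Whether shTRAX acted differently in the genotypes was tested as an interaction. No miRNA passed (edgeR 0 of 689, smallest adjusted p = 0.455, 61 at an unadjusted p under 0.05, and 2 by DESeq2, both lower). The 61 ran from 30 without R6/2 control replicate 2 to 146 without R6/2 shTRAX replicate 1, while the adjusted count stayed at 0 without any 1 library. The smallest p belonged to miR-467a-5p (-1.0 ± 0.25), miR-467b-5p (-1.0 ± 0.25, with near-equal counts), miR-466c-5p (-2.39 ± 0.60), miR-467d-5p (-0.85 ± 0.26) and miR-539-5p (-1.18 ± 0.37). None of the 20 lists passed (adjusted p from 0.108 to 0.918), while 1 did without R6/2 shTRAX replicate 3, miR-125 and miR-99/100 (adjusted p = 0.00206), and 2 did without WT shTRAX replicate 1, that family and miR-29 (both 0.0246). Averaged over genotypes, a contrast added after the data were seen, shTRAX was accompanied by higher miR-496a-3p (1.14 ± 0.16), miR-412-5p (1.09 ± 0.15) and miR-6904-5p (4.25 ± 0.60), all at an adjusted p of 0.00453. That count of 3 was 11 without R6/2 shTRAX replicate 3 and 13 by DESeq2. miR-6904-5p, from a hairpin in an exon of Parp1, stood at no more than 0.215 CPM in any control library, so its fitted value rests on few counts. Across 633 miRNAs the shTRAX effects of the genotypes had a Pearson r of -0.11 and a Spearman rho of -0.22, and 243 of the 633 had the same sign (miRNAs are not independent replicates). Pearson's r was 0.23 without R6/2 shTRAX replicate 3. At an unadjusted p under 0.05, 6 miRNAs went the same way in both, where independent lists give 2.38: miR-496a-3p, miR-412-5p, miR-667-5p, miR-667-3p, miR-323-3p and miR-490-3p. The last 3 were named after their values were seen. The hairpins of miR-496a, miR-412 and miR-667 lie in 1 cluster on chromosome 12, and miR-667-5p and miR-667-3p are arms of 1 hairpin. The 6 are thus not independent, and the value for independent lists is not a fair measure for them.

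**Figure D2:**
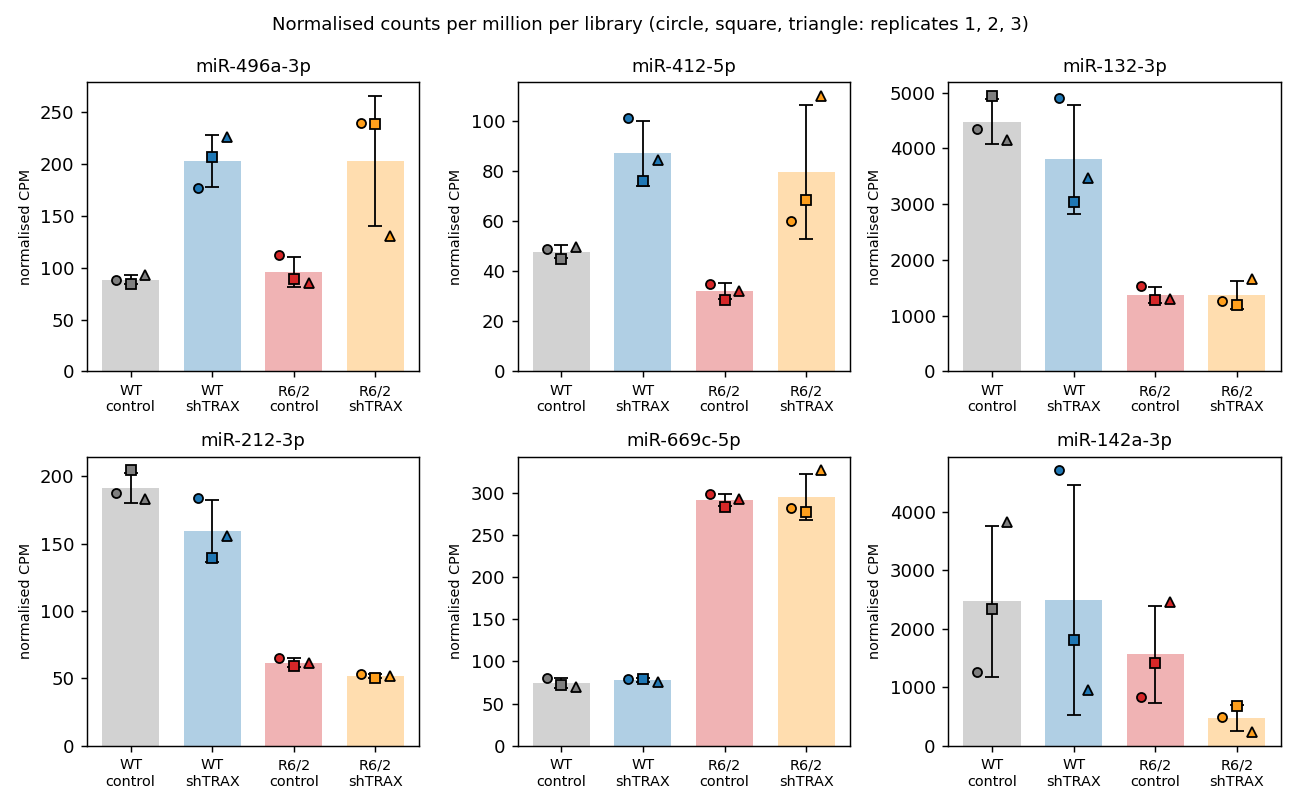
Normalised counts (CPM, y axis) of 6 miRNAs in the 4 groups, where bars show the mean, error bars the SD of 3 libraries and symbols the libraries. miR-496a-3p stood at 176 to 226 CPM in WT shTRAX libraries and 84.0 to 92.8 in WT controls, and miR-669c-5p at 277 to 326 in R6/2 and 69.8 to 80.6 in WT.

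R6/2 was then set against WT under control AAV, which asks how the disease model differs without shTRAX. The GC trend parts these groups too, so genotype and a GC-dependent difference in recovery are confounded in this contrast. The hairpins of the miR-132/212 locus, induced by neuronal activity, fell in R6/2. miR-132-3p went from 4480 ± 409 to 1368 ± 144 CPM (-1.71 ± 0.19, adjusted p = 0.000184), miR-212-3p from 192 ± 11 to 61.8 ± 3.0 CPM (-1.63 ± 0.13, 2.04e-05), miR-132-5p fell by 1.37 and miR-212-5p fell by 1.32 on the log2 scale. miR-221-3p (-0.70 ± 0.12), its neighbour miR-222-5p (-0.82 ± 0.14), miR-344b-3p (-0.68 ± 0.10), miR-344d-3p (-0.84 ± 0.16), miR-22-3p (-0.65 ± 0.13), the muscle miRNA miR-206-3p (-1.29 ± 0.22), miR-6418-3p (-1.29 ± 0.27) and miR-193a-5p (-1.06 ± 0.23) also fell. The 12 higher calls with the smallest p all came from 1 place, a cluster in an intron of Sfmbt2. Its member miR-669c-5p went from 74.1 ± 5.8 to 291 ± 7.5 CPM (1.98 ± 0.12, adjusted p = 1.96e-06), above the WT libraries in 3 of 3 R6/2 libraries. edgeR called 73 of 689 miRNAs, 50 higher and 23 lower, with 165 at an unadjusted p under 0.05 and non-overlapping groups for 48.9% (10% by chance). DESeq2 called 106, with 72 shared. Scaling by total count alone gave 44 higher and 39 lower. GC offsets, added after the data were seen, gave 84 calls, 47 higher and 37 lower, of which 61 were among the 73. With them miR-132-3p (-1.58), miR-212-3p (-1.44) and miR-669c-5p (1.77) kept their calls, and miR-22-3p did not (-0.54, adjusted p = 0.0964).

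The count of 73 fell to 40 and 48 without R6/2 control replicates 2 and 3 and to 45, 44 and 45 without WT control replicates 1, 2 and 3. It rose to 210 without R6/2 shTRAX replicate 3, which is in neither of the compared groups, and these held all 73. The 165 at an unadjusted p under 0.05 ran from 131 to 184 without any other library and was 272 without that one. miR-6418-3p was lost without R6/2 control replicate 1 or 3 or WT control replicate 1, and miR-193a-5p without R6/2 control replicate 1 (adjusted p up to 0.0618 and 0.0558). The other 22 miRNAs of the naming rule kept their call without any 1 library.

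Neuron-enriched miRNAs were lower as a set under control AAV, 5 of 32 past the threshold and 6 adjusted over the list alone (camera adjusted p = 0.00178; 0.235 with an estimated correlation). Activity-induced miRNAs were lower, 4 of 13 by both adjustments (0.0087; 0.227 with an estimated correlation). In both lists the members with the smallest p were the 4 arms of miR-132 and miR-212, which were all 4 of the activity-induced calls. Their hairpins lie together on chromosome 11, at 75173388 to 75173747, so these calls come from 1 locus. Below 0 were 22 of 32 neuron-enriched members (median -0.15) and 9 of 13 activity-induced members (median -0.24). Vascular markers were higher, 13 of 14 above 0 with a median of 0.45 (0.0087; 0.50 with an estimated correlation), and 7 passed adjusted over the list alone. Of them miR-195a-3p rose (0.59 ± 0.16, adjusted p = 0.037), while miR-195a-5p (0.41 ± 0.13), miR-497a-3p (1.30 ± 0.43) and miR-497a-5p (0.79 ± 0.27) did not pass. The miR-195a and miR-497a hairpins lie together on chromosome 11, at 70234717 to 70235135, so these 4 members come from 1 locus. Muscle markers were lower, 6 of 7 below 0 (0.0302, and 0.702 with an estimated correlation), with miR-206-3p past the threshold and 3 members adjusted over the list alone. Short of the threshold were miR-133b-3p (-1.04 ± 0.31), miR-133a-3p (-0.54 ± 0.18) and miR-133a-5p (-0.48 ± 0.36). The hairpins of miR-206 and miR-133b lie in exons of 1 host gene, Gm28653 on chromosome 1, so these members are not independent. Microglia and inflammation markers were lower as a set, 15 of 16 below 0 (0.0302; 0.779 with an estimated correlation), with 0 members past the threshold, also adjusted over the list alone, and values of -1.44 ± 0.50 for miR-147-5p, -0.36 ± 0.17 for miR-146b-5p, -0.81 ± 0.42 for miR-21a-5p and -0.79 ± 0.56 for miR-146a-5p. The summed CPM of this list ranged from 8086 to 17987 in R6/2 controls and from 14559 to 27635 in WT controls. The other 15 lists had adjusted p from 0.0764 to 0.96. With GC offsets the activity-induced (0.0545) and microglia (0.0588) sets did not pass, while miR-147-5p (0.0438) and miR-195a-5p (0.0383) did. The microglia set was lost without R6/2 control replicate 1, R6/2 shTRAX replicate 3 or WT control replicate 3 (up to 0.32) and the muscle set without WT control replicate 1 (0.0546). REST-repressed miRNAs passed without R6/2 control replicate 1 or WT control replicate 2 (lowest 0.0354), choroid markers without R6/2 control replicate 1 or 3 (lowest 0.0189) and let-7 without R6/2 shTRAX replicate 3 or WT control replicate 1 (lowest 0.0136).

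The call of miR-195a-3p was lost without any 1 of 7 libraries (adjusted p up to 0.162): R6/2 control replicates 2 and 3, R6/2 shTRAX replicate 2, the 3 WT controls and WT shTRAX replicate 3. miR-195a-5p passed without any 1 of R6/2 shTRAX replicates 1 and 3 and WT shTRAX replicates 1 and 2 (adjusted p from 0.0075), miR-497a-3p, miR-497a-5p, miR-133b-3p and miR-133a-3p passed without R6/2 shTRAX replicate 3 (0.0095, 0.00108, 0.00241 and 0.00847), and miR-147-5p passed without WT shTRAX replicate 3 (0.0318).

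The Sfmbt2 cluster was examined as a set after these calls were seen. It spans 10466663 to 10518279 on chromosome 2 (GRCm38), inside an intron of Sfmbt2, a polycomb gene, and holds the miR-297, miR-466, miR-467 and miR-669 families. Of its 49 tested members 37 rose in R6/2 under control AAV, 0 fell, and the median was 1.38 (camera adjusted p = 1.15e-36; 0.0137 with an estimated correlation). With GC offsets 30 rose and the median was 1.20. miR-467a-5p and miR-467b-5p (2.16 ± 0.18 and 2.15 ± 0.18) had near-equal counts, as did miR-297a-3p, miR-297b-3p and miR-297c-3p (each 1.60 ± 0.18) and miR-467a-3p and miR-467d-3p (each 1.67 ± 0.24), so single members are uncertain. miR-467d-5p (1.67 ± 0.19), miR-467c-5p (1.57 ± 0.20), miR-467e-5p (1.58 ± 0.21) and miR-669h-5p (1.84 ± 0.26) completed the 12. Summed over the 39 groups left after merging members with near-equal counts, the cluster stood at 266 ± 12 CPM in WT controls, 270 ± 27 in WT shTRAX, 753 ± 17 in R6/2 controls and 629 ± 37 in R6/2 shTRAX libraries (SD, n = 3 each). Members with a mean under 20 counts were not merged, so some of the 39 may share reads. The mean log2 level was 1.08 higher in the 6 R6/2 than in the 6 WT libraries, with an exact permutation p of 0.005 (two-sided, 400 permutations within AAV), for a cluster picked from its calls. The direction of the genotype difference was the same under each scaling.

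**Figure D3:**
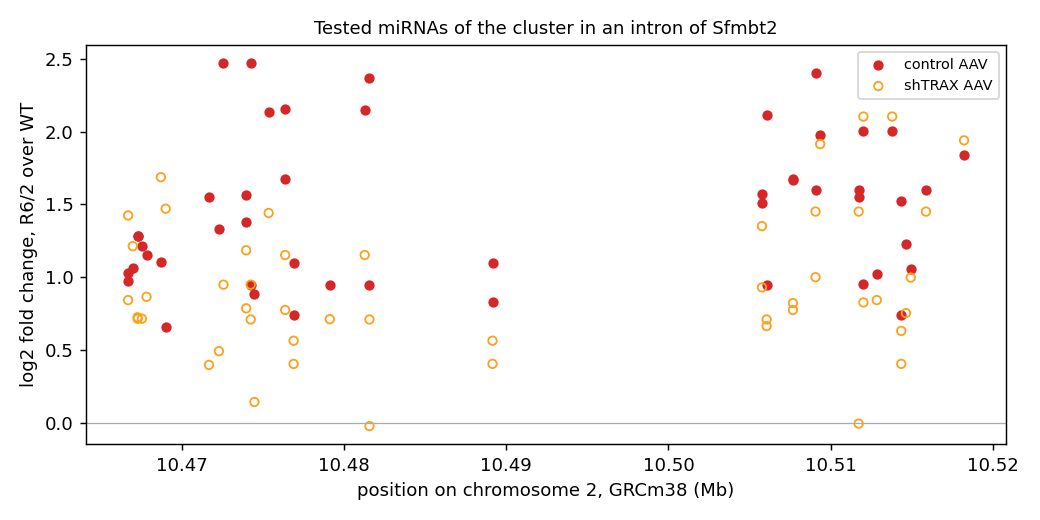
Position on chromosome 2 (GRCm38, Mb) of the 49 tested miRNAs of the cluster in an intron of Sfmbt2 against the log2 fold change of R6/2 over WT. Filled points show control AAV, with a median of 1.38, and open points shTRAX AAV, with a median of 0.83.

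Under shTRAX AAV, R6/2 again had lower miR-212-3p (-1.62 ± 0.13, adjusted p = 2.24e-05), miR-132-3p (-1.48 ± 0.19, from 3804 ± 973 to 1366 ± 252 CPM) and miR-132-5p (-1.33 ± 0.19) than WT. Also lower were miR-344b-3p (-0.80 ± 0.10), miR-344-3p (-0.63 ± 0.13), miR-344h-3p (-2.29 ± 0.41), miR-139-5p (-0.94 ± 0.16), miR-221-3p (-0.67 ± 0.12), miR-222-5p (-0.64 ± 0.14), miR-22-3p (-0.68 ± 0.13), and the Dlk1-Dio3 members miR-411-3p (-1.0 ± 0.18) and miR-381-3p (-0.64 ± 0.13). The Sfmbt2 cluster was higher, 24 of 49 members past the threshold with a median of 0.83 (adjusted p = 0.158 with an estimated correlation). It gave miR-669c-5p (1.92 ± 0.12, 2.66e-06), the 3 miR-297-3p names (1.45 ± 0.18), miR-669h-5p (1.94 ± 0.27), miR-467a-5p and miR-467b-5p (1.15 ± 0.18), miR-467c-5p (1.18 ± 0.20) and miR-466d-3p (0.83 ± 0.14). Other rises were those of miR-679-5p (1.2 ± 0.19), miR-181c-3p (0.55 ± 0.11) and miR-195a-3p (0.81 ± 0.16). edgeR called 95 of 689, 55 higher and 40 lower, with 225 at an unadjusted p under 0.05 (171 to 250 without 1 library) and non-overlapping groups for 30.5% (10% by chance). Scaling by total count gave 35 higher and 45 lower, and moved the median over all miRNAs from 0.04 to -0.07. A fit of only the 6 shTRAX libraries called 2, and the count was 51, 38 and 40 without WT shTRAX replicates 1, 2 and 3. It was 141 without R6/2 shTRAX replicate 3, of which 88 were among the 95, and 132 by DESeq2, with 93 shared. GC offsets gave 110, with 86 shared, and ended the calls of miR-181c-3p (0.33, adjusted p = 0.145), let-7f-5p (0.48, 0.102) and miR-206-3p (-0.67, 0.0891), while miR-125b-5p (0.0395) and miR-133b-3p (0.0486) passed.

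Of the lists, 9 passed under shTRAX AAV, and 0 with an estimated correlation (adjusted p from 0.297). REST-repressed (7 of 22 lower, adjusted p = 0.00263), neuron-enriched (7 of 32 lower, 0.00827) and activity-induced miRNAs (4 of 13 lower and 1 higher, 0.0118) were lower as sets, and the 4 arms of miR-132 and miR-212, miR-212-5p among them (-0.97 ± 0.24), stood in all 3. Adjusted over the list alone, 7, 7 and 5 were lower, and 1, 0 and 1 higher. Estimated correlations gave adjusted p of 0.364, 0.364 and 0.297. The 4 arms of miR-132 and miR-212, from 1 locus, were all 4 of the lower calls among activity-induced miRNAs. The Dlk1-Dio3 cluster was lower as a set (10 of 88 lower and 5 higher by both adjustments, adjusted over the list alone included; 0.0118, and 0.364 with an estimated correlation), with miR-127-3p (0.64 ± 0.15) and miR-540-3p (1.18 ± 0.30) among the higher. Microglia and inflammation markers were lower (3 of 16, 5 adjusted over the list alone; 0.00827, and 0.576 with an estimated correlation), with miR-142a-3p (-2.40 ± 0.65), miR-21a-5p (-1.51 ± 0.43) and miR-147-3p (-1.95 ± 0.55) past the threshold and miR-155-5p (-3.15 ± 1.0) short of it. The summed CPM of this list was 33009 in WT shTRAX replicate 1 against 12887 and 10026 in replicates 2 and 3, and 6804 to 9750 in R6/2 shTRAX libraries. Muscle markers were lower (1 of 7, 5 adjusted over the list alone, camera adjusted p = 0.00827, and 0.364 with an estimated correlation), with miR-206-3p at -0.78 ± 0.22 past the threshold. The values of miR-133b-3p (-1.02 ± 0.31), miR-133a-3p (-0.58 ± 0.18) and miR-133a-5p (-1.01 ± 0.37) did not pass. The miR-206 and miR-133b hairpins share a host gene, so these members are not independent.

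Families that were higher in R6/2 under shTRAX AAV were let-7 (5 of 21, 7 adjusted over the list alone; adjusted p = 0.0325, and 0.364 with an estimated correlation), miR-125 and miR-99/100 (3 of 11, 5 adjusted over the list alone; 0.0188, and 0.364) and miR-181 (2 of 10 by both adjustments, also adjusted over the list alone; 0.0345, and 0.387). Rises were found for let-7e-5p (0.99 ± 0.20), let-7b-5p (0.75 ± 0.19), let-7c-5p (0.56 ± 0.14), let-7f-5p (0.44 ± 0.11), miR-125a-3p (1.30 ± 0.26), miR-125a-5p (1.08 ± 0.32), miR-99b-3p (0.92 ± 0.22) and miR-181d-5p (0.48 ± 0.13). The log2 ratio of R6/2 shTRAX replicate 3 to the mean of replicates 1 and 2 was 1.47 for miR-125a-5p, 1.12 for miR-125a-3p and 0.94 for miR-99b-3p. It was 0.40 to 0.87 for these let-7 members and -0.15 for miR-181d-5p, so the size of most of these rises leans on that library. Over the alternatives, miR-125a-5p ran from 0.41 to 1.29, let-7b-5p from 0.41 to 0.87 and let-7e-5p from 0.62 to 1.11. miR-125b-5p (0.52 ± 0.17), miR-181d-3p (0.67 ± 0.39) and miR-181a-2-3p (0.59 ± 0.41) did not pass. The hairpins of miR-99b, let-7e and miR-125a lie together in Spaca6 on chromosome 17, at 17830188 to 17830879 (GRCm38). The 3 calls of the miR-125 and miR-99/100 list and that of let-7e-5p thus come from 1 locus. The let-7b and let-7c-2 hairpins also share a host gene, on chromosome 15, so these calls may not be independent. A 3p arm of let-7c-1 was measured too, so the counts of let-7c-5p cannot be placed at that host gene alone. The other 11 lists had adjusted p from 0.121 to 0.731. Among them were the vascular markers, which had passed under control AAV. Here 9 of 14 lay above 0, with a median of 0.05, 2 past the threshold and higher, and a camera adjusted p of 0.516. With GC offsets the miR-181 set did not pass (0.0615). The let-7 set was lost without R6/2 shTRAX replicate 1 or 2 or WT shTRAX replicate 1 (up to 0.209), the miR-181 set without any 1 of the R6/2 shTRAX libraries or WT shTRAX replicates 2 and 3 (up to 0.13), the microglia set without R6/2 shTRAX replicate 1 or WT shTRAX replicate 1 (up to 0.168), and the Dlk1-Dio3 set without WT shTRAX replicate 3 (0.0933). Choroid markers passed without R6/2 control replicate 2 or WT shTRAX replicate 1 (lowest 0.0245), and epithelial and olfactory markers without R6/2 shTRAX replicate 1 or WT shTRAX replicate 3 (lowest 0.00652).

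Of the 39 calls named under shTRAX AAV, 26 were kept without any 1 library. Leaving out WT shTRAX replicate 1, 2 or 3 each ended the calls of let-7b-5p, let-7c-5p, miR-99b-3p and miR-540-3p (adjusted p up to 0.0741), replicate 1 or 2 those of let-7f-5p and miR-127-3p (up to 0.0639), and replicate 1 that of miR-212-5p (0.0549). miR-206-3p was lost without R6/2 shTRAX replicate 1 or 2 or WT shTRAX replicate 2 or 3 (up to 0.112). miR-142a-3p was lost without any 1 of 6 libraries, namely R6/2 control replicate 2, R6/2 shTRAX replicates 1 and 3, WT control replicate 2 and WT shTRAX replicates 1 and 2 (up to 0.13). miR-147-3p was lost without any 1 of 8, the same set without R6/2 shTRAX replicate 1 and with R6/2 control replicate 3, R6/2 shTRAX replicate 2 and WT shTRAX replicate 3 (up to 0.126). miR-125a-5p was lost without any 1 of 9 libraries, all but those of R6/2 shTRAX (up to 0.121), miR-181d-5p without any 1 of 9, all but R6/2 control replicate 1, R6/2 shTRAX replicate 3 and WT shTRAX replicate 1 (up to 0.121), and miR-21a-5p without any 1 of 10, all but WT control replicate 3 and WT shTRAX replicate 3 (up to 0.145). miR-125b-5p and miR-133b-3p passed without any 1 of the R6/2 shTRAX libraries (from 0.0291 and 0.0344), miR-133a-3p and miR-133a-5p passed without R6/2 shTRAX replicate 2 (0.0371 and 0.0329), and miR-155-5p passed without WT shTRAX replicate 3 (0.037).

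The genotype differences under both AAVs were compared, since their groups share no libraries, although the fit of 12 libraries gives them 1 estimate of the spread. There were 27 miRNAs higher in both and 15 lower in both, where independent lists give 3.99 and 1.34, and 0 went opposite ways at the threshold. Most of the overlap of higher miRNAs was 1 locus, since 22 of the 27 were members of the Sfmbt2 cluster, several with near-equal counts, and 1 more, miR-466a-3p, had counts near-equal to those of members. Without these, counted after the data were seen, 4 were higher in both, miR-679-5p, miR-195a-3p, miR-26b-5p and miR-1224-5p, where independent lists give 0.563, and 15 were lower in both, where they give 1.44. Both arms of miR-132 and of miR-212 are among the 15, so these are not independent either. Of the 73 called under control AAV, 71 had the same sign under shTRAX AAV, and 34 of 35 outside the cluster. Fold changes from separate fits of 6 libraries had a Pearson r of 0.43 across 635 miRNAs and of 0.30 across 594 outside the cluster (miRNAs are not independent replicates). The 73 had a median signed log2 difference of 1.23 under control AAV, where they were selected, and 0.75 under shTRAX AAV.

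**Figure D4:**
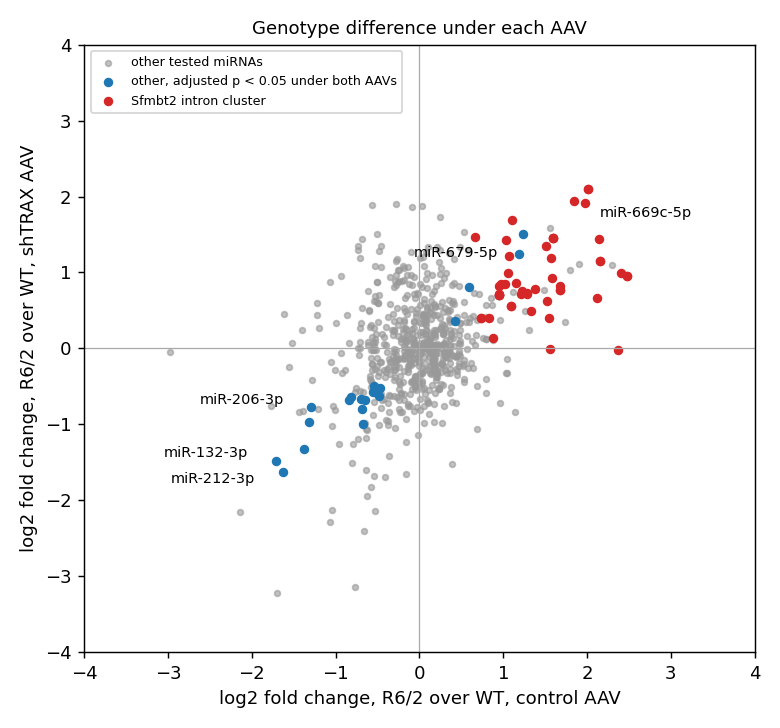
Log2 fold change of R6/2 over WT under control AAV (x axis) and shTRAX AAV (y axis) for 689 miRNAs, with red points for the Sfmbt2 intron cluster and blue points for other miRNAs past the threshold under both. miR-132-3p lay at -1.71 and -1.48, and miR-669c-5p at 1.98 and 1.92.

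The shTRAX effect in R6/2 and the genotype difference under control AAV use the same R6/2 controls. Their log2 fold changes had a Pearson r of -0.32 and a covariance of -0.105, where unchanged groups simulated against those controls gave -0.50 and -0.064.

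Minor arms of hairpins were compared with major arms, since the complex of TRAX and translin is reported to act on passenger strands of small RNA duplexes and on precursors. Under shTRAX the median difference of the minor from the major arm was -0.10 in R6/2 (204 hairpins, exact permutation p = 0.1) and 0.05 in WT (205 hairpins, p = 0.3, exact permutation). R6/2 differed from WT by 0.04 under control AAV (215 hairpins, p = 0.2, exact permutation) and by -0.07 under shTRAX AAV (p = 0.2, exact permutation), the latter 0.03 without R6/2 shTRAX replicate 3. Single libraries set the size of these values. The R6/2 value was -0.04 without R6/2 shTRAX replicate 3, and the WT value was 0.01 without WT shTRAX replicate 2 and 0.03 without WT control replicate 3. The value under control AAV was 0.07 without R6/2 control replicate 1. Under shTRAX AAV it was -0.12 and -0.11 without R6/2 shTRAX replicates 1 and 2, and -0.11 and -0.04 without WT shTRAX replicates 1 and 2. No p under 0.1 was possible, so these tests cannot pass the threshold.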

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

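Tests chosen only after the result was seen were the set test and the pooled permutation test of the Sfmbt2 cluster, the 3 versions of the test for a swapped label, the search for Tsnax sequence, the comparison with the rest of the Dlk1-Dio3 cluster, and the splits for shTRAX and for the difference between genotypes. The GC offsets, the merging of near-equal miRNAs, the library weights and the mean shTRAX effect were also added after the data were seen. What the GC offsets and the merging were to show for the Sfmbt2 cluster, miR-496a-3p and R6/2 shTRAX replicate 3 was written before those results.

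The miRNAs of the Sfmbt2 intron cluster differed in their shTRAX effect between R6/2 and WT by a set test of the interaction at the preset correlation, and not with an estimated one. The median log2 difference, R6/2 minus WT, was -0.42 (camera adjusted p = 6.45e-07 over 7 clusters, 0.774 with an estimated correlation). The median was -0.28 without R6/2 shTRAX replicate 3 and -0.17 with GC offsets, and it kept its sign under each scaling. Within R6/2 the median shTRAX effect was -0.37, with 44 of 49 members below 0 (camera adjusted p = 1.5e-09; 0.610 with an estimated correlation). It was -0.25 without R6/2 shTRAX replicate 3 and -0.10 with GC offsets. Within WT it was 0.07 over 39 tested members (camera adjusted p = 0.229). On the mean log2 level per library, the exact permutation p of the shTRAX effect was 0.1 in R6/2, the smallest possible, and 0.8 in WT. The cluster was picked by its rise in the R6/2 controls. Both the R6/2 effect and the difference between genotypes subtract those controls, so selection alone can push both below 0.

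The higher level of this cluster in R6/2 under control AAV was weighed against technical causes. A GC trend parts the R6/2 and WT controls, with a Spearman rho of -0.36 to -0.30 against 0.04 to 0.19. The cluster members were among the miRNAs it was computed on, so their rise can itself add to the trend. With GC offsets the median was 1.20 and 30 of 49 members were higher instead of 37, so a GC trend is argued against as the whole cause. The offsets were fitted with the cluster included and can remove part of a real rise. Whether a part of the rise comes from GC-dependent recovery therefore cannot be told. With miRNAs of near-equal counts merged, 26 groups of the cluster were higher, which argues against 1 signal counted many times through near-equal counts. Reads shared in part between members were not tested. The sequences repeat in the genome, so reads from other repeats stay open. A higher output of the locus in R6/2 may be the biological cause, and Sfmbt2 mRNA is not measured here.

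R6/2 shTRAX replicate 3 stood apart. A smooth on arm GC content removed 21.4% of its squared log2 deviation (95% bootstrap interval 16.7 to 26.8, 1000 draws), so most of the deviation was left. That deviation includes counting noise, and the arm only stands in for the mature sequence. The share therefore cannot exclude a GC trend as the whole cause. For a swapped label, 3 versions were tried after the result was seen, on a scale from 0 (WT control) to 100 (R6/2 control): 28.6 over 210 calls, 37.8 over 63 with at least 1 log2 and 60.9 over the 24 of the naming rule. Other R6/2 libraries stood at 86.8 or more on the first version and WT libraries at up to 33.4, while 18 of the 24 lay on the R6/2 side against 0 in every WT library, with miR-669c-5p at 326 CPM (WT 69.8 to 80.6) and miR-132-3p at 1654 (WT 3038 to 4939). The versions differ, so a wrong label, a mixed sample or a difference in RNA extraction, of which the labels name 2 kinds without assigning them, could not be settled and may each contribute.

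The rise of miR-496a-3p under shTRAX was weighed against 3 causes. Its longest run shared with a Tsnax transcript was 8 bases, and 30.7% of arms share no longer run, which argues against reads of the hairpin RNA counted as this miRNA if the hairpin matches Tsnax. With GC offsets the log2 fold change in WT was 1.14 ± 0.12 (adjusted p = 0.0145). The median of 87 other Dlk1-Dio3 members in WT was 0.12 (quartiles -0.02 to 0.27), so a rise of the whole cluster does not account for it. An effect of less TRAX on this miRNA may be the biological cause, but a sequence effect of the shTRAX construct apart from TRAX was not tested.

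Other splits of the same libraries were counted. For shTRAX in R6/2 the real split gave 0 calls by edgeR (68 at an unadjusted p under 0.05, 13 by DESeq2) and the highest other 2. As the real count is 0, that 10 of 10 splits gave at least as many was fixed and says nothing about chance. In WT the real split gave 1 and the highest other 1 (2 of 10). For the genotype difference the real split gave 73 and the highest other 0 under control AAV (1 of 10), and 95 and 1 under shTRAX AAV (1 of 10). With 10 splits a share under 0.05 cannot be had. For the difference of effects the real split gave 0 calls by edgeR (61 at an unadjusted p under 0.05, 2 by DESeq2) and the highest other 3, and that 100 of 100 splits gave at least 0 was likewise fixed.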

How the results depend on the processing

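GC offsets, merging of near-equal miRNAs and library weights were chosen after the data were seen. Where values differ below, the cause was not tested unless stated.

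For shTRAX in R6/2 the count of 0 became 13 with DESeq2, 1 in the fit of 12 libraries and 6 with library weights. Leaving out 1 library gave 0 to 4. The lists went from 0 to 2 with the replicate block, 1 with GC offsets and 0 to 2 without 1 library. miR-760-3p reversed to -0.0412 with library weights and ranged from -0.0564 to 2.30 without 1 library, because R6/2 shTRAX replicate 3 alone is high.

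For shTRAX in WT the count of 1 became 4 without a low-count filter, 4 with DESeq2, 0 in the fit of 12 libraries, 6 with library weights and 0 to 57 without 1 library. The 3 lists became 0 with an estimated correlation, 0 with fry and 3 to 5 without 1 library.

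Under control AAV the 73 became 46 without a low-count filter, 151 with each precursor kept as deposited (repeated names are counted again), 232 in the fit of 6 libraries, 263 with library weights and 40 to 210 without 1 library. The 5 lists became 0 with an estimated correlation, 3 with fry, 0 with the higher arm alone and 3 with GC offsets. Under shTRAX AAV the 95 became 149 with each precursor kept, 59 with the replicate block, 2 in the fit of 6 libraries, 180 with library weights and 38 to 141 without 1 library. The 9 lists became 0 with an estimated correlation and 5 with the higher arm alone.

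For the difference of effects the count of 0 became 2 with DESeq2 and 2 with library weights, and the lists 0 to 2 without 1 library. The minor arm difference under shTRAX AAV ranged from -0.12 to 0.0281 without 1 library and reversed without R6/2 shTRAX replicate 3.

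Replicate numbers do not pair the libraries: 1 of 12 correlated best with its own number. With the number as a block the counts were 0, 1, 59, 59 and 0. For named miRNAs, the alternatives fixed beforehand kept direction and side of the threshold 2056 times, passed it newly 77 times, lost it 143 times and reversed 1 time, and those added later did so 311, 27, 7 and 1 times. Pseudocounts of 0.1 and 5 were to be run only if RPM alone was deposited, and were not run.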

Other observations

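Marker sums varied within groups. Hindbrain and spinal Hox miRNAs summed to 83.2 CPM in WT shTRAX replicate 1 and to 6.38 to 37.4 in the other libraries. Oligodendrocyte markers summed to 6042 CPM in R6/2 shTRAX replicate 3 and to 8846 to 10860 in the others. Choroid plexus and ependyma markers summed to 5723 to 6811 CPM in the R6/2 shTRAX libraries.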
